A study of Mus musculus with 6 samples.

How the data were processed

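Gene expression was measured in 6 pools of mouse cumulus-oocyte complexes, each pool hybridised as biotin-labelled cRNA to an Affymetrix mouse genome array. A cumulus-oocyte complex is the oocyte with the specialised granulosa cells, the cumulus, around it. Per the labels' protocols, immature females had received equine chorionic gonadotropin (eCG), which stimulates follicle growth, for 48 h. The 3 groups of 2 arrays were complexes without human chorionic gonadotropin (hCG, which triggers ovulation), complexes 8 h after hCG and complexes 16 h after hCG. Each array was assigned to its group and replicate number from its title. Per the labels' protocols, the complexes without hCG came from ovaries, and those of both later times were described as taken from the oviduct, so the place of collection went with the hormone. The 8 h site is in doubt, since ovulation is usually not complete by then. If those complexes came from ovaries, the place of collection went with 16 h against 8 h instead, and with 16 h against no hCG. The labels call the complexes without hCG expanded, a wording left unexplained here. Nothing in the labels says that replicates came from separate animals or collections, so the p-values measure only the spread between these samples, which can be technical.

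The deposited table held log2 intensities, 1 value per probe set and array, from 3.32 to 15.5. The software, background correction, normalization and summary were not given in the sources used here. The log2 scale was read from the values themselves. Array medians lay between 6.14 and 6.27, a range of 0.125, which is under the limit of 0.2 set before the data were examined, so the values were taken as comparable between arrays and used as they were. No detection calls were used here, so the signal over background is unknown. Fold changes that involve a low value are uncertain in size and may be understated. The number of arrays, 2 per group, limits the precision of every estimate.

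Of 45101 probe sets, 64 were controls and were left out. Gene names came from the platform's annotation table, which gave 34945 probe sets 1 symbol, 932 several and 9160 none. Of those with 1 symbol, 34754 matched a current mouse gene by gene number, and 0 symbols needed an update. No gene was named from a probe set with several symbols, and genes without a probe set named in that table were not analysed here. Probe sets with a mean over the 6 arrays under the 40th percentile, 5.62, were called too dim and not tested. This left 27022 probe sets, which covered 13559 genes by 1 probe set each. For a gene with several probe sets, the one with the highest mean was used.

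Group means were fitted to all 6 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 3 residual degrees of freedom and 6.43 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 27022 probe sets of each comparison, and a probe set was called changed at an adjusted p under 0.05. All adjusted p-values of genes in the text come from this limma fit. The 3 comparisons, 8 h against no hCG, 16 h against 8 h and 16 h against no hCG, share arrays. For the time courses, 20 simulations of unchanged probe sets gave the values that shared arrays alone produce, and 1 array of the 8 h group was used per interval as an alternative added later.

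Before the data were examined, 23 gene lists were fixed, 16 of processes and 7 of cell types that a complex or its collection could include. They were cumulus matrix and expansion, EGF-like factors, prostaglandins, hyaluronan precursors, immediate-early and ERK feedback genes, the progesterone receptor and its downstream genes, steroidogenesis, cholesterol biosynthesis, glycolysis, granulosa genes, meiotic arrest, cell cycle, proteases and inhibitors, endoplasmic reticulum stress, innate immunity, and neuronal and secretion genes. The cell types were oocyte, theca and stroma, leukocytes, endothelium, erythrocytes, ovarian surface epithelium and oviduct epithelium. The innate immune and neuronal lists are themes this study is known for, so their direction is not independent evidence. Of its genes with a named probe set, the progesterone receptor list shares 5 with other lists. Other lists overlap too, as Has2 is on the cumulus matrix and hyaluronan precursor lists and Cyp17a1 on the steroidogenesis and theca lists. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 66 tests of 22 lists in 3 comparisons. The erythrocyte list had 2 tested genes and no list test. An estimated correlation and limma's fry were alternatives. Another 6 lists were chosen after the genes with the largest changes had been seen.

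The named genes were set by a rule fixed before the data were examined. Per comparison it took the 8 highest and 8 lowest log2 changes among called genes whose brighter group mean reached the 75th percentile, 8.5. It added up to 4 members with the largest changes per list, and Zp3 and Has2 as checks of the labels. Where other genes are named, the text says so. No called named gene had a tested probe set called in the opposite direction. Epcam, not called at 16 h against no hCG (−0.29 ± 0.22, adjusted p = 0.355), had another probe set called upward (0.58 ± 0.18, adjusted p = 0.028).

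The scripts were tested on simulated arrays with the real means and fitted spread, in which 200 probe sets were changed. Of those changed by 2 on the log2 scale, 100% were recovered for 8 h against no hCG, 98.5% for 16 h against 8 h and 98.5% for 16 h against no hCG. At a change of 1, the shares were 35.8%, 56.7% and 22.4%, and at 0.5 they were 0% in each. Among 92, 109 and 83 calls, 2, 6 and 3 were unchanged probe sets. In the data far more probe sets were called, 33.9%, 18.2% and 37.3% in the 3 comparisons. Adjustment was therefore stricter in the simulation, and its shares do not give the recovery in the data. Alternatives varied the normalization, the filter on dim probe sets, the arrays in the fit, a replicate block, the prior, the threshold, probe sets prone to cross-hybridisation, the probe set per gene, the list test and each array in turn. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.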

Results

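Transcripts of pooled mouse cumulus-oocyte complexes were measured before hCG and 8 h and 16 h after it, with 2 arrays per group. By correlation, the arrays of a group resembled each other more than arrays of different groups. Pearson's r across all non-control probe sets, which are not independent replicates, was 0.991 without hCG, 0.996 at 8 h and 0.995 at 16 h, and between 0.943 and 0.979 across groups. The median difference between the arrays of a group was 0.19 on the log2 scale without hCG, 0.13 at 8 h and 0.15 at 16 h. Across groups it was between 0.17 and 0.29, and 2 pairs of an 8 h and a 16 h array differed less by this measure than the pair without hCG. As checks of the labels, the hyaluronan synthase Has2 was 5.72 ± 0.07 (SD, n = 2) without hCG, 8.96 ± 0.06 at 8 h and 7.06 at 16 h. The zona pellucida gene Zp3, made by the oocyte, was 12.27 ± 0.27, 9.67 ± 0.15 and 7.77. Changes below are differences of log2 group means ± SE of the limma fit, with n = 2 arrays per group. For genes with a dim group they are measured differences of uncertain size and rank, since the signal over background is unknown and a low value may understate a change.

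The first comparison asked how the complexes had changed 8 h after hCG. The largest measured rises were those of Sult1e1, the estrogen sulfotransferase (log2 change 7.93 ± 0.21), Nts, which encodes neurotensin (7.73 ± 0.26), and Lyve1, a hyaluronan receptor (7.47 ± 0.23). Star, which moves cholesterol into mitochondria for steroid synthesis, rose by 6.41 ± 0.26, the chemokine receptor gene Cxcr4 by 6.35 ± 0.17 and the prostaglandin synthase gene Ptgs2 by 6.24 ± 0.17. Snap25, a membrane fusion protein of secretory vesicles, rose by 6.22 ± 0.35, and Ptx3, a pentraxin of the expanded cumulus matrix, by 5.98 ± 0.22. The largest falls were those of Slfn4 (−4.47 ± 0.17), the hedgehog ligand gene Ihh (−4.43 ± 0.17), Fam81a (−4.20 ± 0.17) and the vesicular monoamine transporter gene Slc18a2 (−4.04 ± 0.22). Otor, the carbonic anhydrase gene Car14, the cytochrome P450 gene Cyp2s1 and Kctd14 fell by between 4.0 and 3.85. Lyve1, Cxcr4, Ptgs2 and Snap25 had means of 4.89, 4.99, 5.5 and 4.16 without hCG, and Otor of 5.53 at 8 h, all under the limit for dim probe sets (5.62), as was the lower mean of 14 of the 92 genes named by rule in this comparison. Adjusted p-values of these 16 genes, by limma with Benjamini-Hochberg adjustment, ran from 5.65e-08 to 2.72e-06. In all, 9167 of 27022 probe sets changed, 4429 upward and 4738 downward, and 2108 of the first and 2119 of the second by at least 2-fold. By gene, 2292 rose and 2777 fell. Without replicate 2 of the 8 h group, and so with the spread taken from the other groups alone, the count was 6109.

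Genes of cumulus matrix and expansion, the hyaluronan-rich coat that forms around the oocyte before ovulation, rose as a group at 8 h. Of 14 tested, 10 rose and 2 fell, with the same counts adjusted over the list alone, and the median change was 2.42 (camera, adjusted p = 9.4e-06; adjusted p = 0.218 with an estimated correlation). Beside Ptgs2 and Ptx3, the hyaluronan cross-linking gene Tnfaip6 rose by 4.59 ± 0.19, the hyaluronan receptor gene Cd44 by 3.57 ± 0.34 and Has2 by 3.24 ± 0.15. On the hyaluronan precursor list, 5 of 9 genes rose and 0 fell (6 and 0 adjusted over the list alone). They included Ugdh (1.25 ± 0.16) and Gfpt2 (1.17 ± 0.15). Has2, the synthase that uses these precursors, is on this list too and had its largest change, so both lists overlap. That list had camera adjusted p = 0.00428, with adjusted p = 0.273 with an estimated correlation. Of 12 EGF-like factors and receptors, 6 rose and 2 fell (6 and 3 adjusted over the list alone), led by the ligand genes Ereg (5.93 ± 0.15), Btc (4.83 ± 0.21) and Epgn (4.21 ± 0.28) and the feedback inhibitor gene Errfi1 (3.21 ± 0.15). As a list they were not called (camera, adjusted p = 0.109), but were without replicate 2 of the group without hCG (0.0353) and without replicate 1 of the 8 h group (0.0376), in a range of 0.00148 to 0.373 over all alternatives. Of 13 prostaglandin genes, 6 rose and 3 fell, the same adjusted over the list alone, without a list call (adjusted p = 0.284). The prostaglandin transporter gene Slco2a1 rose by 4.47 ± 0.21 and the prostaglandin-degrading enzyme gene Hpgd fell (−2.33 ± 0.15).

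The progesterone receptor and genes downstream of it at ovulation rose together at 8 h. Of 14 tested, 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 3.01 (camera, adjusted p = 4.99e-11; adjusted p = 0.218 with an estimated correlation). Beside Cxcr4, Snap25 and Ereg, the cGMP-dependent kinase gene Prkg2 rose by 5.94 ± 0.16. Immediate-early and ERK feedback genes rose in 11 of 26 cases and fell in 3, the same adjusted over the list alone, with Egr3 (5.20 ± 0.19) and the ERK phosphatase gene Dusp4 (4.29 ± 0.15) in front. This list had camera adjusted p = 0.00433 and adjusted p = 0.39 with an estimated correlation. Extracellular proteases and their inhibitors rose in 12 of 24 cases and fell in 3 (14 and 3 adjusted over the list alone). The protease inhibitor gene Timp1 rose by 3.82 ± 0.15, and the metalloprotease genes Adam8 and Adamts1 by 3.80 ± 0.19 and 2.84 ± 0.19 (list adjusted p = 0.000425; adjusted p = 0.218 with an estimated correlation).

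Cholesterol biosynthesis genes rose in 14 of 19 cases at 8 h and fell in 0, the same adjusted over the list alone (median 0.87; camera, adjusted p = 3.26e-05; adjusted p = 0.358 with an estimated correlation). The largest changes were in Cyp51 (2.14 ± 0.17), Dhcr7 (1.70 ± 0.16), Msmo1 (1.67 ± 0.17) and Lss (1.66 ± 0.16). Of 15 steroidogenesis genes, 8 rose and 4 fell (9 and 5 adjusted over the list alone), without a list call (adjusted p = 0.068). The list was called without the filter on dim probe sets (adjusted p = 0.0379), with that filter at the 60th percentile (0.0469), without replicate 2 of the group without hCG (0.0471), without replicate 1 of the 8 h group (0.0434) and by fry (0.0101), in a range of 0.0101 to 0.551 over all alternatives. The progesterone-inactivating enzyme gene Akr1c18 rose by 2.28 ± 0.15 and the electron carrier gene Fdx1 by 2.11 ± 0.18, whereas the androgen-forming enzyme gene Cyp17a1 fell (−2.30 ± 0.23). Cyp17a1 is also a theca marker and is counted again among the theca and stroma markers below, where it had the largest fall. Of 18 glycolysis and glucose uptake genes, 3 rose and 9 fell (3 and 10 adjusted over the list alone), among them the lactate transporter genes Slc16a1 (−2.05 ± 0.20) and Slc16a3 (−1.69 ± 0.24) and the phosphofructokinase genes Pfkp (−1.56 ± 0.15) and Pfkl (−1.52 ± 0.15). Camera gave this list an adjusted p of 0.0664, with 0.035 after quantile normalization, 0.0345 without the filter on dim probe sets and 0.0483 without replicate 2 of the 8 h group, in a range of 0.0046 to 0.386 over all alternatives. Among 23 endoplasmic reticulum stress genes, 4 rose and 0 fell (3 and 0 adjusted over the list alone; list adjusted p = 0.146), including Edem1 (1.10 ± 0.17).

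Granulosa and preovulatory cumulus genes fell at 8 h. Of 22 tested, 16 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of −1.62 (camera, adjusted p = 2.42e-08; adjusted p = 0.265 with an estimated correlation). Beside Ihh, the inhibin subunit gene Inhbb, the cyclin gene Ccnd2 and Npr2, the receptor that makes cGMP in cumulus cells, fell by 2.54, 2.54 and 2.53, with SEs of 0.20, 0.16 and 0.18. Cell cycle genes fell in 27 of 33 cases and rose in 0 (31 and 0 adjusted over the list alone), with a median of −1.08 (adjusted p = 6.94e-10; adjusted p = 0.358 with an estimated correlation). The replication genes Mcm3 (−1.71 ± 0.15) and Mcm6 (−1.67 ± 0.17) were among them. Of 13 genes that hold the oocyte in meiotic arrest or end that arrest, 2 rose and 6 fell, the same adjusted over the list alone (list adjusted p = 0.185). The gap junction gene Gja4 fell (−3.30 ± 0.18), as did the natriuretic peptide gene Nppc (−2.17 ± 0.16), and the cAMP phosphodiesterase gene Pde4d rose by 3.69 ± 0.17.

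Innate immune and cytokine genes rose in 13 of 31 cases at 8 h and fell in 3 (13 and 4 adjusted over the list alone; camera, adjusted p = 0.0041; adjusted p = 0.218 with an estimated correlation). Neuronal and regulated secretion genes rose in 9 of 25 cases and fell in 4, the same adjusted over the list alone, without a list call (adjusted p = 0.0945, and 0.0197 without replicate 1 of the group without hCG, in a range of 0.0056 to 0.373 over all alternatives). The study is known for immune and neuronal genes in these samples, so the direction of both lists is not independent evidence. In the first list, the sialomucin gene Cd34 rose by 4.81 ± 0.23, the transcription factor gene Runx1 by 3.52 ± 0.23 and the cytokine gene Il6 by 3.48 ± 0.21. Of 16 tested leukocyte markers, 1 rose and 0 fell, the same adjusted over the list alone, with a median of −0.02 and a mean of 0.03 (camera upward, adjusted p = 0.864). That gene was the macrophage growth factor receptor gene Csf1r (1.36 ± 0.19), of whose 3 probe sets 2 were not called. In the second list, the granin genes Scg2 and Chgb, proteins of secretory granules, rose by 3.13 ± 0.20 and 3.03 ± 0.22.

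Oocyte markers fell at 8 h in 24 of 24 tested cases, the same adjusted over the list alone, with a median of −2.18 (camera, adjusted p = 4.51e-15; adjusted p = 0.218 with an estimated correlation). They ranged from −3.01 ± 0.18 for the zona gene Zp1 to −0.94 ± 0.16 for Figla, a transcription factor gene picked here because it marks that end. This fall went with each of the changes above. Of 6 ovarian surface epithelium markers 3 fell and 0 rose, the same adjusted over the list alone (adjusted p = 0.0373; adjusted p = 0.274 with an estimated correlation). That call was lost without replicate 2 of the group without hCG (adjusted p = 0.088), without replicate 1 of the 8 h group (0.0751) and without probe sets prone to cross-hybridisation (0.0567), in a range of 0.00589 to 0.274 over all alternatives. Theca and stroma markers fell in 4 of 11 cases and rose in 0, the same adjusted over the list alone (adjusted p = 0.11, with 0.0294 without the filter on dim probe sets and 0.0224 without replicate 2 of the 8 h group, in a range of 0.0224 to 0.49 over all alternatives). Of 8 oviduct epithelium markers 1 rose and 3 fell (adjusted p = 0.109), and of 6 endothelial markers 1 rose and 0 fell (adjusted p = 0.387), each the same adjusted over the list alone. The endothelial gene that rose was the cadherin gene Cdh5 (2.86 ± 0.25). The erythroid gene Alas2 had a log2 change of −0.68 ± 0.24 and was not called (adjusted p = 0.0565). It was called with only the compared groups in the fit and without either 16 h array (0.0293), with the dim filter at the 60th percentile (0.0493) and with the mean of its probe sets (0.0447), in a range of 0.0128 to 0.288 over all alternatives. The 2 tested erythrocyte genes were too few for a list test.

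**Figure D1:**
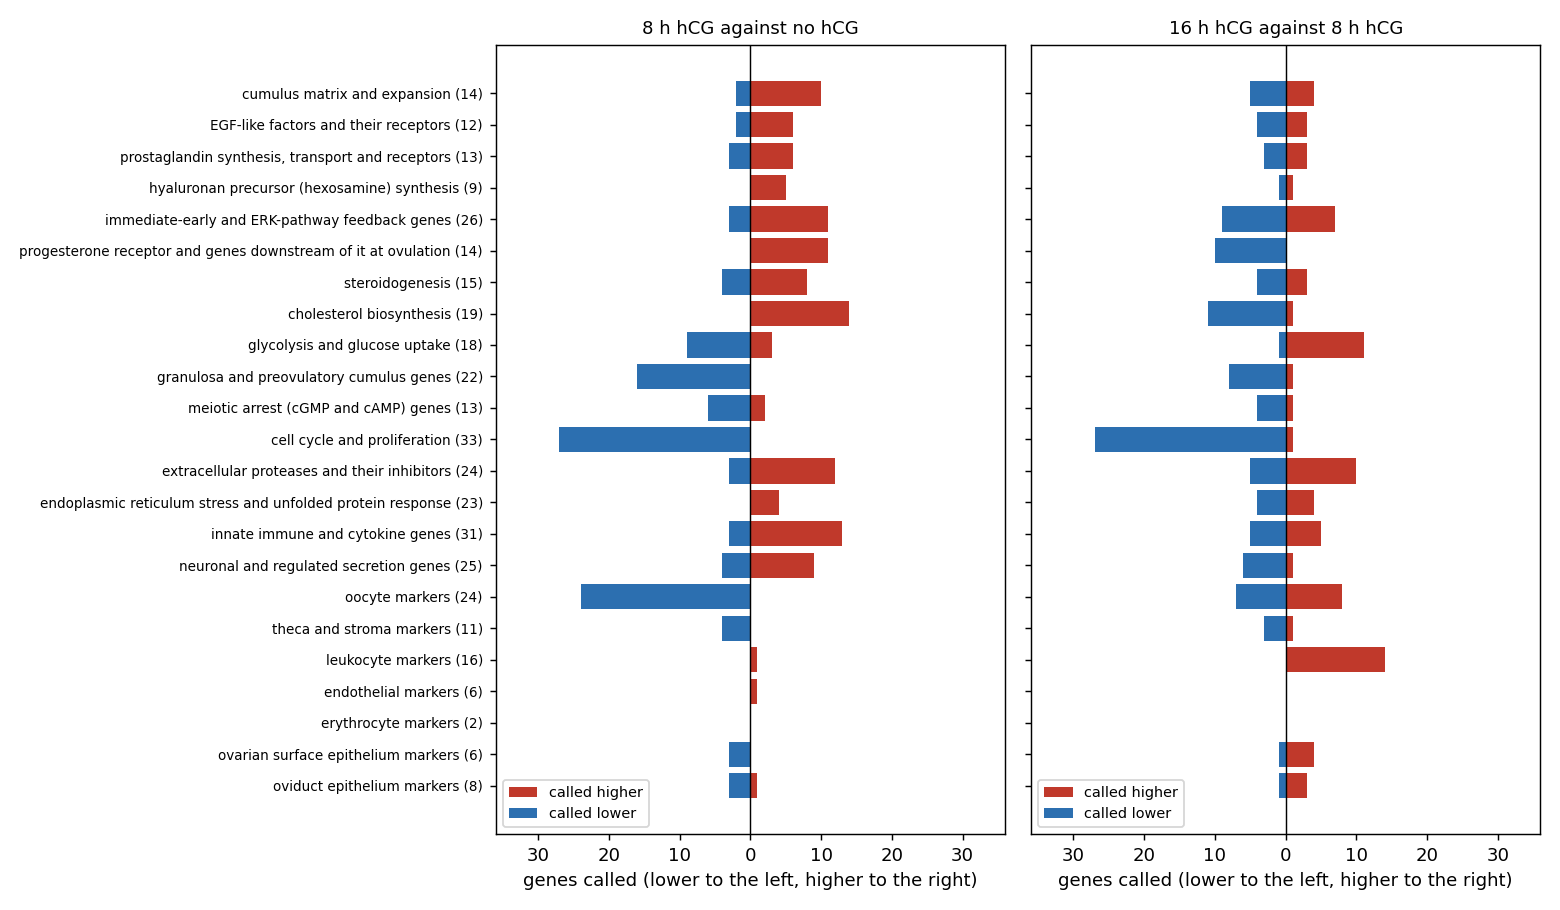
Number of genes called higher (red, to the right) and lower (blue, to the left) in each of the 23 gene lists at 8 h against no hCG (left panel) and at 16 h against 8 h (right panel), with the number of tested genes per list in brackets. Oocyte markers fell in 24 of 24 cases at 8 h and split into 8 higher and 7 lower from 8 h to 16 h, and leukocyte markers rose in 14 of 16 cases from 8 h to 16 h.

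The second comparison asked what changed between 8 h and 16 h after hCG. The largest rises were those of Pdcd1, which encodes the immune checkpoint receptor PD-1 (4.30 ± 0.18, 19.6-fold), and the acute-phase gene Saa3 (4.21 ± 0.20, 18.5-fold). Ovgp1, a glycoprotein secreted by the oviduct, rose by 3.85 ± 0.50, the iron exporter gene Slc40a1 by 3.52 ± 0.30 and the interferon-induced gene Oasl2 by 3.49 ± 0.25. Sh3bgr and Tgfbi rose by 3.90 ± 0.20 and 3.59 ± 0.18. Lyz1 rose by 3.47 ± 0.30, an uncertain value because Lyz2 has a nearly identical sequence. The largest falls were those of Lyve1 (−5.90 ± 0.23), the glutathione transferase genes Gsta2 and Gsta4 (−5.39 ± 0.21 and −5.01 ± 0.16), the ferritin receptor gene Scara5 (−4.80 ± 0.15), Cd34 (−4.74 ± 0.23) and the tight junction gene Cldn1 (−4.62 ± 0.16). Gsta2 is uncertain too, for the same reason. Apela, which encodes a ligand of the apelin receptor, and Tmem255a followed at −4.39 ± 0.15 and −4.31 ± 0.17. Cldn1, Apela and Tmem255a had means of 4.74, 5.13 and 4.23 at 16 h, under the limit for dim probe sets, as was the lower mean of 7 of the 99 genes named by rule. Adjusted p-values of these 16 genes, by limma with Benjamini-Hochberg adjustment, ran from 7.32e-07 to 0.000628. In all, 4922 probe sets changed, 2638 upward and 2284 downward, and by gene 1598 rose and 1236 fell. The count was 2518 without replicate 1 and 2819 without replicate 2 of the 8 h group, and 2648 without replicate 1 and 2784 without replicate 2 of the 16 h group, each with the spread taken from the groups left with 2 arrays.

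Progesterone receptor genes and cholesterol biosynthesis genes, both higher at 8 h, fell from 8 h to 16 h. Of 14 genes of the first list, 10 fell and 0 rose, the same adjusted over the list alone, with a median of −1.28 (camera, adjusted p = 9.85e-09; adjusted p = 0.218 with an estimated correlation). Snap25 fell (−4.25 ± 0.35), as did Cxcr4 (−3.94 ± 0.17), the transcription factor gene Zbtb16 (−3.30 ± 0.16) and Pgr itself (−2.40 ± 0.19). Cholesterol biosynthesis genes fell in 11 of 19 cases and rose in 1 (12 and 1 adjusted over the list alone), with a median of −0.82 (adjusted p = 3.34e-05; adjusted p = 0.358 with an estimated correlation), led by Msmo1 (−1.54 ± 0.17) and Mvk (−1.34 ± 0.17). Glycolysis genes rose in 11 of 18 cases and fell in 1 (12 and 2 adjusted over the list alone), with a median of 0.59 (adjusted p = 9.33e-05; adjusted p = 0.235 with an estimated correlation). Pfkp rose by 2.18 ± 0.15, Slc16a3 by 2.11 ± 0.24 and Pfkl by 1.95 ± 0.15. Cell cycle genes fell in 27 of 33 cases and rose in 1 (28 and 1 adjusted over the list alone), with Cdc6 at −2.66 ± 0.19 and Rrm2 at −1.87 ± 0.26 (adjusted p = 8.86e-14; adjusted p = 0.274 with an estimated correlation). Granulosa genes fell in 8 of 22 cases and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.00363; adjusted p = 0.39 with an estimated correlation). The FSH receptor gene Fshr fell (−2.36 ± 0.15), and the BMP receptor gene Bmpr1b rose by 1.40 ± 0.20.

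Leukocyte markers rose from 8 h to 16 h. Of 16 tested, 14 rose and 0 fell, the same adjusted over the list alone, with a median of 1.78 (camera, adjusted p = 3.98e-11; adjusted p = 0.218 with an estimated correlation). The lysozyme gene Lyz2 (uncertain, as Lyz1 is nearly identical) rose by 3.32 ± 0.26, the pan-leukocyte gene Ptprc by 2.58 ± 0.24, H2-Aa, an antigen presentation gene, by 2.51 ± 0.27 and the complement gene C1qc by 2.42 ± 0.16. Innate immune genes rose in 5 of 31 cases and fell in 5 (5 and 6 adjusted over the list alone; list adjusted p = 0.546), with Cd52 (2.71 ± 0.19) and the endotoxin receptor gene Cd14 (2.04 ± 0.18) rising beside Pdcd1. Neuronal and secretion genes fell in 6 of 25 cases and rose in 1 (6 and 3 adjusted over the list alone; list adjusted p = 0.139). Among them Scg2 fell (−2.45 ± 0.20), as did Nts (−2.26 ± 0.26). As these are the themes the study is known for, neither direction is independent evidence. Ovarian surface epithelium markers rose in 4 of 6 cases and fell in 1, the same adjusted over the list alone (adjusted p = 0.00828; adjusted p = 0.235 with an estimated correlation), with the keratin genes Krt18 (3.22 ± 0.21) and Krt8 (2.44 ± 0.15) in front. The 1 that fell, named here as the exception, was Upk3b (−0.89), with a dim mean of 4.77 at 16 h. Another 4 of the 10 markers were too dim to test. Of 8 oviduct epithelium markers 3 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.202). Theca and stroma markers fell in 3 of 11 cases and rose in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0172; adjusted p = 0.376 with an estimated correlation). This last call was lost without replicate 2 of the 8 h group (adjusted p = 0.0779), with a dim filter at the 60th percentile (0.0548) and by fry (0.0682), in a range of 0.00136 to 0.376 over all alternatives. The labels place both collections in the oviduct, but the 8 h site is in doubt, and if it was the ovary the place of collection changed along with these markers.

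Oocyte markers moved both ways from 8 h to 16 h, with 8 of 24 higher and 7 lower (11 and 7 adjusted over the list alone; camera, adjusted p = 0.875). The maternal-effect genes Padi6 and Ooep fell (−2.22 ± 0.18 and −1.93 ± 0.19), as did the zona genes Zp2 (−2.17 ± 0.15) and Zp3 (−1.90 ± 0.26). The 8 that rose, named here after their values had been seen, were Gdf9, Bmp15, Mos, Oosp1, H1f8, Tcl1, Btg4 and Bpgm, with changes from 1.16 for Gdf9 to 1.45 for Tcl1. Of 14 cumulus matrix genes 4 rose and 5 fell (7 and 5 adjusted over the list alone; adjusted p = 0.795), among them Has2 (−1.90 ± 0.15) and Adamts1 (−1.44 ± 0.19). Of 26 immediate-early genes 7 rose and 9 fell (8 and 12 adjusted over the list alone; adjusted p = 0.139, with 0.0261 without replicate 2 of the 16 h group and a range of 0.0261 to 0.601 over all alternatives), with Atf3 at −2.57 ± 0.33 and Nr4a2 at 2.48 ± 0.18. Of 13 meiotic arrest genes 1 rose, the cGMP phosphodiesterase gene Pde5a (2.99 ± 0.17), and 4 fell, the same adjusted over the list alone (adjusted p = 0.271). Steroidogenesis genes rose in 3 of 15 cases and fell in 4 (3 and 5 adjusted over the list alone; adjusted p = 0.947), with Akr1c18 at 2.62 ± 0.15 and Star at −1.93 ± 0.26. Lists of EGF-like factors (adjusted p = 0.376), prostaglandins (0.947), hyaluronan precursors (0.772), proteases (0.195), endoplasmic reticulum stress (0.918) and endothelium (0.737) were not called. For the cumulus matrix, steroidogenesis and endoplasmic reticulum stress lists the median was above 0 and the camera direction was down, and the oocyte list had a median of 0.11 and a mean of −0.01.

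**Figure D2:**
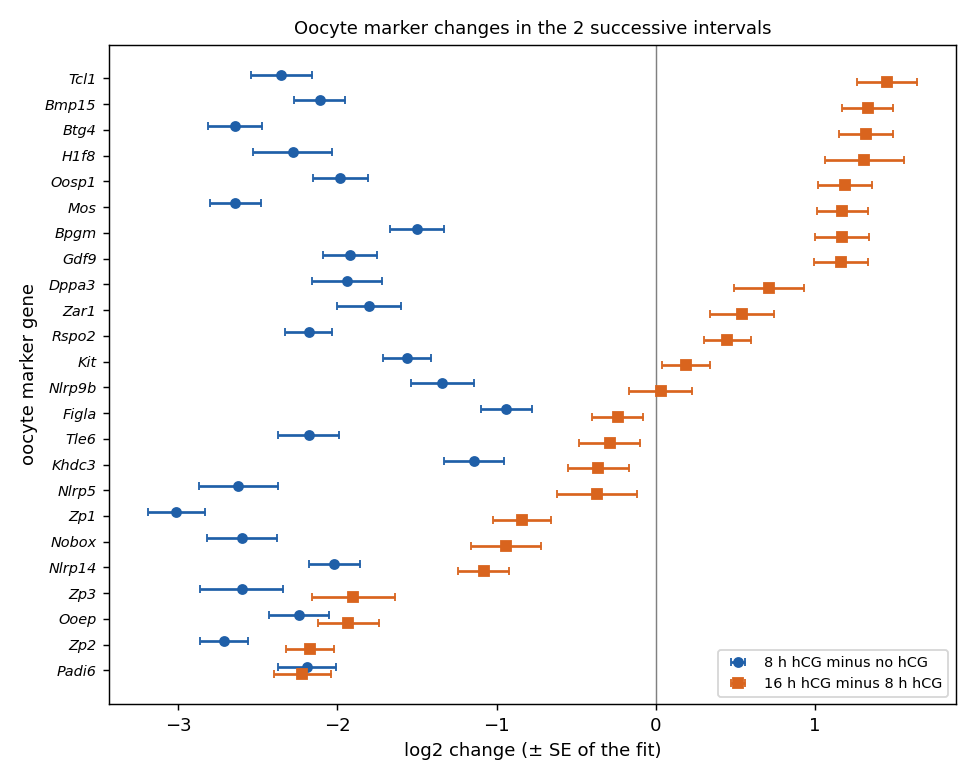
Log2 change of each of the 24 tested oocyte markers from no hCG to 8 h (blue circles) and from 8 h to 16 h (orange squares), with bars for the SE of the limma fit (n = 2 arrays per group) and the genes in order of the second change. In the first interval each marker lies below 0, from −3.01 to −0.94, and in the second the markers spread from −2.22 for Padi6 to 1.45 for Tcl1.

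The third comparison gave the net change at 16 h against no hCG. Ptgs2 had the largest measured rise (7.26 ± 0.17), then the Wnt antagonist gene Sfrp2 (6.74 ± 0.18), Pdcd1 (6.38 ± 0.18), Tmem71 (6.02 ± 0.27), Cited4 (5.74 ± 0.22), Tnfaip6 (5.49 ± 0.19) and Nts (5.47 ± 0.26). Emp1 rose by 5.43 ± 0.28 on 1 of its 2 tested probe sets and was not called on the other. The largest falls were those of Gtsf1, a gene of the germline small RNA pathway (−6.23 ± 0.16), Itih5 (−5.60 ± 0.19), Car14 (−5.56 ± 0.16), Umodl1 (−5.12 ± 0.23) and Slc18a2 (−5.09 ± 0.22). Fam81a, Fbxw21 (uncertain, one of a family of similar genes) and the pluripotency gene Dppa2 fell by 5.04, 5.0 and 4.98. Ptgs2, Sfrp2 and Tnfaip6 without hCG (5.5, 4.98 and 5.01) and Itih5, Slc18a2 and Dppa2 at 16 h (5.01, 5.05 and 4.52) were under the limit for dim probe sets, as was the lower mean of 17 of the 97 genes named by rule. Adjusted p-values of these 16 genes, by limma with Benjamini-Hochberg adjustment, ran from 5.3e-08 to 8.39e-07. In all, 10072 probe sets changed, 5128 upward and 4944 downward, and by gene 2825 rose and 2818 fell.

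At 16 h, cumulus matrix genes were higher than without hCG in 11 of 14 cases and lower in 2, the same adjusted over the list alone (median 1.94; camera, adjusted p = 0.000108; adjusted p = 0.235 with an estimated correlation). Progesterone receptor genes were higher in 10 of 14 cases and lower in 1, the same adjusted over the list alone (adjusted p = 7.46e-05; adjusted p = 0.218 with an estimated correlation). Genes of the hyaluronan precursor list, which includes Has2, rose in 6 of 9 cases and fell in 0, the same adjusted over the list alone (adjusted p = 0.00433; adjusted p = 0.273 with an estimated correlation). Proteases and inhibitors rose in 16 of 24 cases and fell in 2 (17 and 2 adjusted over the list alone; adjusted p = 7.46e-05; adjusted p = 0.218 with an estimated correlation), with Timp1 (4.66 ± 0.15) and the lysosomal protease gene Lgmn (3.60 ± 0.16) in front. Cell cycle genes fell in 33 of 33 cases, the same adjusted over the list alone, with a median of −1.66 (adjusted p = 1.22e-16; adjusted p = 0.265 with an estimated correlation) and Cdc6 at −4.23 ± 0.19. Granulosa genes fell in 20 of 22 cases and rose in 0, the same adjusted over the list alone (median −2.01; adjusted p = 6.21e-10; adjusted p = 0.235 with an estimated correlation), with Inhbb at −3.96 ± 0.20 and Fshr at −3.54 ± 0.15. Akr1c18 rose by 4.90 ± 0.15, the largest change among 15 steroidogenesis genes, of which 8 rose and 4 fell, the same adjusted over the list alone (list adjusted p = 0.109).

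Oocyte markers were lower at 16 h than without hCG in 23 of 24 cases and higher in 0, the same adjusted over the list alone (median −1.42; camera, adjusted p = 1.86e-12; adjusted p = 0.235 with an estimated correlation). The change was −4.88 ± 0.15 for Zp2 and −4.50 ± 0.26 for Zp3. Leukocyte markers were higher in 14 of 16 cases and lower in 0 (14 and 2 adjusted over the list alone; adjusted p = 5.81e-07; adjusted p = 0.218 with an estimated correlation). Beside them, innate immune genes rose in 13 of 31 cases and fell in 3 (14 and 3 adjusted over the list alone; adjusted p = 0.00363; adjusted p = 0.218 with an estimated correlation), with Cd52 (4.09 ± 0.19) and Cd14 (3.07 ± 0.18) in front after Pdcd1 and Ptx3. Neuronal and secretion genes rose in 8 of 25 cases and fell in 5, the same adjusted over the list alone (list adjusted p = 0.376). The direction of both lists is again not independent evidence. Theca and stroma markers fell in 6 of 11 cases and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0119; adjusted p = 0.373 with an estimated correlation), with the collagen gene Col1a2 at −2.63 ± 0.23. The remaining lists were not called. Among them, oviduct epithelium and endothelial markers had medians of −0.13 and −0.02 with camera directions upward (adjusted p = 0.958 and 0.669).

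Set side by side, the changes of the successive intervals tended to oppose each other. Of the 4429 probe sets that rose by 8 h, 1042 fell again by 16 h, 547 rose further and 2840 were not called in the second interval. Of the 4738 that fell by 8 h, 905 rose again, 520 fell further and 3313 were not called. Another 1186 rose and 722 fell after 8 h without a call in the first interval. Independent calls would have given 374 probe sets up then down, 463 down then up, 432 up then up and 400 down then down. Courses in 1 direction thus also exceeded independent calls, though by less than the opposed ones. The counts moved with single arrays. In that order they were 599, 404, 232 and 211 without replicate 1 of the 8 h group and 662, 444, 259 and 224 without replicate 2 of it. They were 680, 405, 279 and 305 without replicate 1 of the 16 h group and 644, 545, 319 and 247 without replicate 2 of it. Independent calls would then have given 139 to 208 up then down, 160 to 256 down then up, 151 to 238 up then up and 147 to 223 down then down. Counts of probe sets called in the second interval alone ranged from 570 to 1697 upward and from 296 to 1126 downward over the arrays left out. Both comparisons use the 8 h arrays, with opposite sign, so chance errors there also produce opposed changes. Across probe sets the correlation of both changes was −0.213, against −0.498 for simulated unchanged probe sets, and the covariance was −0.108 against −0.0221, a difference of −0.0854. In a split chosen after the data had been seen, 1 array of the 8 h group served the first change and the other the second, so that both changes shared no array. The correlation was then −0.217 and the covariance −0.109 with replicate 1 in the first change, and −0.143 and −0.077 with replicate 2 there. Calls were not counted in this split, since each change then rests on 1 array at 8 h, so part of the excess of opposed calls may come from the shared arrays.

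**Figure D3:**
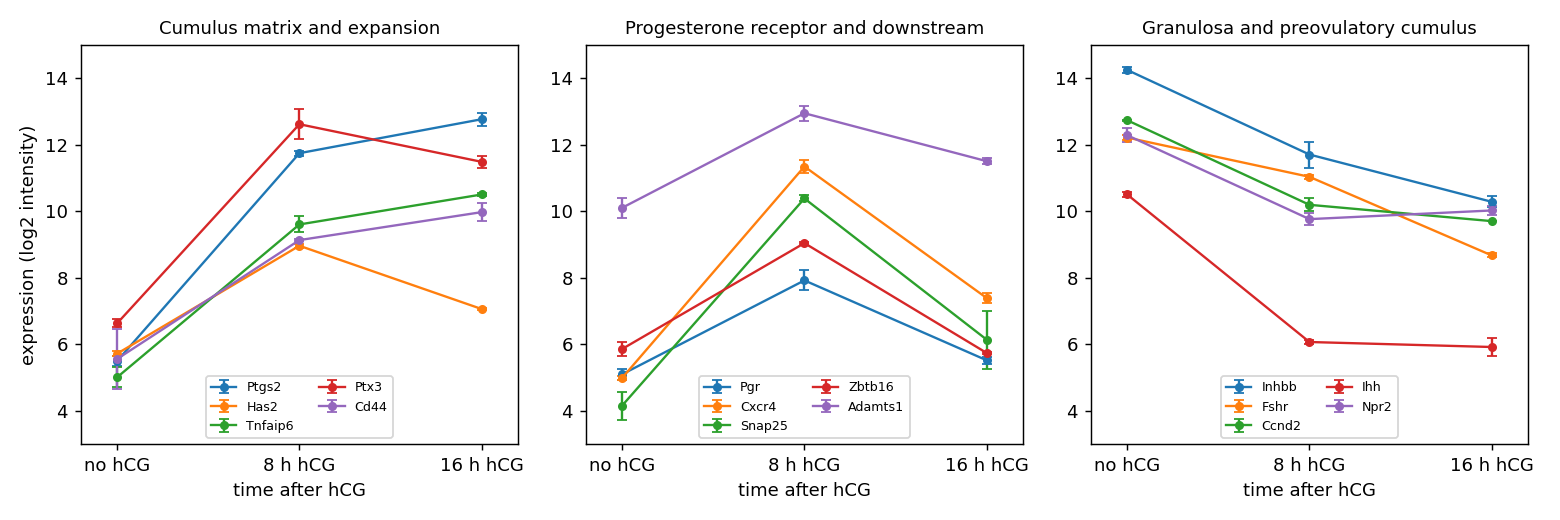
Log2 intensity (group mean, bars for the SD of n = 2 arrays) of genes named in the text without hCG, 8 h after hCG and 16 h after hCG, for cumulus matrix and expansion (left), the progesterone receptor and genes downstream of it (middle) and granulosa and preovulatory cumulus genes (right). Ptgs2 is higher at both later times, Has2 and Snap25 are highest at 8 h, and Inhbb and Fshr are lower at each successive time.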

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

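Of 267 calls among 288 results for 173 named genes, 240 were kept under each alternative and 246 each time 1 array was left out. A log offset was not tried because the values were already log2. Leaving out 1 array leaves a group with 1 array; that array is assumed to vary like the other groups, which alone give the spread. Then 8 h against no hCG gave 6109 to 9450 changed probe sets (2948 to 4951 higher), and 16 h against 8 h gave 2518 to 6340 (1254 to 3411 higher, 1187 to 2929 lower). The 6340 came from leaving out an array without hCG, which is not in that comparison, and equals the count with only the compared groups in the fit; leaving out an array of the compared groups gave at most 2819. Time courses ranged from 599 to 1255 up then down, 404 to 1143 down then up, 232 to 788 up then up, 211 to 675 down then down, 570 to 1697 not called then up and 296 to 1126 not called then down. A further limit of at least 2-fold, stricter by construction, left 4227 (2108 higher, 2119 lower), 2076 (1075, 1001) and 4728 (2440, 2288) changed probe sets in the 3 comparisons, and 484, 272, 190, 142, 613 and 375 in the time courses, in the order above. An adjusted p under 0.01 left 2755 for 16 h against 8 h (1460, 1295) and 618, 414, 267, 247, 779 and 430 in the time courses. Fitting only the groups compared gave 1169 probe sets not called then down; the cause was not tested. Camera called 11, 8 and 10 lists in the 3 comparisons and 0, 0 and 0 with an estimated correlation, where the lowest adjusted p was 0.218. That alternative rests on 3 residual degrees of freedom and has little power. Its lack of calls neither bears out the preset calls nor shows that correlation between genes removed them. The cause was not tested. Fry, which does not compare a list with other genes, called 19 and 20 lists in the comparisons against no hCG. Without probe sets named _x_at and _s_at, Epcam at 16 h against no hCG turned from −0.29, not called, to 0.58, called (limma, adjusted p = 0.0287). Another probe set then stood for the gene. Without replicate 2 of the group without hCG its change was −0.66, so its direction is not settled. The oviduct list at 16 h against no hCG (median −0.13) was downward by fry and upward by camera. The cause was not tested. With the replicate number as a block, 10117, 5812 and 11045 probe sets changed. Deviations of arrays with the same number correlated at 0.468, 0.001 and 0.135. As 1 pair was not over 0.1, the limit fixed for pairing, the numbers were not taken to pair the arrays, though 0.468 leaves a link of the first pair open. An 18S ribosomal RNA control was also lower in replicate 1 without hCG, at 8 h and at 16 h. It was 11.19, 11.59 and 11.14 there, against 12.60, 12.09 and 12.62 in replicate 2. Other control measures did not all follow the number, so a link by replicate number stays open. The block changed no list call and added calls of Alas2 at 8 h (adjusted p = 0.0128) and from 8 h to 16 h (0.0392) and of Krt19 at 8 h (0.0477). Over all alternatives, calls of single lists ended in 38 cases, 29 of them with the estimated correlation, and arose in 35, 22 of them by fry. Signal over background is unknown here, which limits what can be said of dim genes.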

Other observations

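The lists and tests in this part were chosen after the results had been seen, apart from the oocyte, leukocyte, oviduct and innate immune lists, which were fixed before the data were examined. Genes induced by interferon rose from 8 h to 16 h in 19 of 23 tested cases and fell in 0, with a median of 1.84 (camera, adjusted p = 1.17e-13; adjusted p = 0.35 with an estimated correlation). Oasl2 (3.49 ± 0.25), Trim34a (3.17 ± 0.23), Rtp4 (3.11 ± 0.22) and the RNA sensor gene Ifih1 (2.56 ± 0.21) led them, whereas at 8 h against no hCG 2 of the 23 rose and 3 fell. The arrays at 16 h stood apart on this list, with 21 of 23 genes higher in replicate 1, a median difference of 0.53 and a median SD of 0.38, against 0.14 without hCG and 0.13 at 8 h. Without replicate 1 of the 16 h group 16 rose, with a median of 1.21, and without replicate 2 of it 19 rose, with a median of 2.32. The list was called each time 1 array was left out (adjusted p from 3.65e-17 to 1.32e-13). Lysosomal genes rose in 14 of 26 cases from 8 h to 16 h and fell in 0 (adjusted p = 3.18e-06; adjusted p = 0.35 with an estimated correlation), with the cathepsin gene Ctss, which leukocytes also express, at 3.23 ± 0.50. Without replicate 1 or 2 of the 8 h group the median lysosomal change was 0.48 and 0.59. Without replicate 1 or 2 of the 16 h group it was 0.49 and 0.55. Fewer lysosomal genes were called with any of these arrays left out. Leukocyte markers rose in 14 of 16 cases in this interval, and whether leukocytes account for the lysosomal rise was not tested. Among those markers Lyz2 was 8.34 at 8 h and 11.66 at 16 h, and Laptm5 was 11.11 and 11.00 on its brightest probe set, while 2 of its 3 other tested probe sets rose after 8 h (0.83 ± 0.19 and 3.47 ± 0.27).

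Heat shock genes rose in 6 of 16 cases at 8 h against no hCG and fell in 1 (adjusted p = 0.0317; adjusted p = 0.35 with an estimated correlation). From 8 h to 16 h they fell in 7 cases and rose in 0 (adjusted p = 5.88e-05; adjusted p = 0.343 with an estimated correlation), with 4 falling without replicate 1 of the 16 h group. At 16 h against no hCG 1 was higher and 4 lower, without a list call (adjusted p = 0.506). The inducible chaperone gene Hspa1a rose by 2.53 at 8 h and then fell (−4.03 ± 0.31). Its values are uncertain because Hspa1b, counted beside it, has a nearly identical sequence. Its arrays also lay apart, with SDs of 0.52 without hCG and 0.64 at 8 h. Of 14 glutathione transferase genes, 6 rose and 5 fell by 8 h (adjusted p = 0.424), and 2 rose and 4 fell from 8 h to 16 h (adjusted p = 0.0821), without a list call. The second test passed without replicate 1 of the 16 h group (adjusted p = 0.0458, in a range of 0.0458 to 0.153 over the arrays left out). In that interval 5 rose and 5 fell without either array of the group without hCG, 1 rose and 4 fell without replicate 2 of the 8 h group or of the 16 h group, and 1 rose and 5 fell without replicate 1 of the 16 h group. With all arrays, the 4 that fell after 8 h, named after their values had been seen, were Gsta2, Gsta4, Gstm1 and Gstm2, all higher at 8 h than without hCG, with Gstm1 at 2.34 and then −2.89 ± 0.23. The Gstm1 probe set is of a kind prone to cross-hybridisation. The 2 that rose after 8 h were Mgst2 (2.46 ± 0.17) and Mgst3 (0.66 ± 0.17). At 16 h against no hCG, 3 of the 14 were higher and 8 lower (median −0.88), without a list call (camera, adjusted p = 0.0821). Of 29 ribosomal protein genes 0 changed from 8 h to 16 h by limma (0 at an unadjusted p under 0.05; fry, adjusted p = 0.807). Of 35 oxidative phosphorylation genes 2 fell, Cycs and Cox5a, but 0 without either 16 h array or without replicate 2 of the 8 h group and 1 without replicate 1 of it. Their list was not called (adjusted p = 0.0821), but passed without replicate 1 of the 16 h group (0.0467, in a range of 0.0467 to 0.2 over the arrays left out). The immediate-early genes Fos, Egr1 and Jun were already bright without hCG, at 14.12, 13.83 and 12.76, and were not called at 8 h.

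Oocyte markers fell together by 8 h and then split. A smaller share of oocyte RNA at 8 h may underlie the first step, as all 24 fell, but a shared loss should move them alike. Their SD of 0.53 exceeded 1.5 times the median SE (0.27), and array compression of dim and bright probe sets could widen it, so loss of share and regulation cannot be told apart. A first limit of 3 SEs (0.54) was dropped after the SD had been seen just under it. From 8 h to 16 h, 8 rose and 7 fell with an SD of 1.22, which argues against a changed oocyte share as the whole cause, and selective loss or polyadenylation of oocyte messages stays open and untested.

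Interferon-induced genes at 16 h could come from leukocytes collected with the complexes. Leukocyte markers, none of them on the interferon list, rose by a median of 1.78 (bootstrap SE 0.35 over genes). This was above 0.5 times the interferon list's 1.84 (0.92), the limit set for that explanation. The limit was set after the data had been seen and without a stated basis, so passing it decides little. No test here separates leukocytes from a response of the cumulus cells. Between the arrays at 16 h, the interferon list differed by a median of 0.53 and the leukocyte markers by 0.01. Of the 16 markers 8 were higher in replicate 1, so they showed no general difference in leukocytes between these arrays. A difference in 1 leukocyte type stays open, and 1 pair of arrays excludes nothing for that difference or for the rise. For the 13 innate immune genes that rose at 8 h (median 1.37), the leukocyte markers argue against a general gain of leukocytes. Of those 16 markers 1 rose, and their median was −0.02 (bootstrap SE 0.097 over genes). The 13 genes were picked by their rise, so their median is high by selection. As the markers mix leukocyte types, a gain of 1 type stays open, and the macrophage gene Csf1r rose by 1.36 on its brightest probe set. Time after hCG remains an untested biological explanation for the rises of the interferon and innate immune genes. If the 8 h complexes came from ovaries, a change in the place of collection stays open too for the rise at 16 h.

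The rise of Ovgp1 by 16 h might reflect oviduct epithelium collected with the complexes. Of 7 other oviduct epithelium markers tested, 2 rose, Cdh1 and Krt8, both also on the ovarian surface epithelium list, and Cldn3 fell (−1.20 ± 0.17). The 5 that were too dim to test, Foxj1, Pax8, Sox17, Dynlrb2 and Wfdc2, moved by at most 0.21. With so few informative markers, and with the 8 h collection site in doubt, carry-over and expression in the complexes cannot be told apart.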
